A study of Mus musculus with 6 samples.

How the data were processed

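The series holds 6 RNA-seq libraries of colon organoids from C57BL/6J mice in 2 groups, 3 without treatment (Ctrl) and 3 treated with TNF for 24 hours. Per the labels' protocols, crypts were embedded in Matrigel, total RNA was extracted with Trizol and libraries were made with standard Illumina protocols. Strandedness was not given in the sources used here. Per the submitters' processing notes, reads were handled with cutadapt (version 1.9) and FastQC, and the genome build was GRCm38. The aligner, the program that counted fragments, its treatment of reads shared by several genes and the annotation release were not given in the sources used here.

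The authors deposited 1 table of 29940 genes with 1 value per gene and library, called normalized counts by its name. The unit was inferred from the values. Each value times the exonic length of the gene's listed transcripts, summed over genes, came to 9.59e+08 to 9.64e+08 per library, close to the 1000000000 that FPKM must give, while the plain sums of 327883 to 336220 rule out CPM and TPM. The deposited values were therefore treated as FPKM, normalized by the authors per kilobase of exon and by the fragments of the library. Gene positions and biotypes came from GENCODE M21 on GRCm38, a reference whose release may differ from the authors' own, in which 29862 of the gene identifiers and 86953 of 87601 transcript identifiers were found.

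Depth was recovered from the low values. Low values of genes of at least 300 bases with a single exon and a single transcript were used, 823 to 935 per library. They were compared with whole multiples of 1 base of sequence. Of these values, 72.4% to 75.8% lay within 0.1 of a whole number, where a step unrelated to them gives 20%. The step was fitted to the lower part of these same values, so some excess over 20% was built in. The step gave 4.18 to 4.80 gigabases per library, and the commonest low value stood for 149 bases, taken as 1 read, so 1 FPKM in a transcript of 1 kilobase stands for 28.1 to 32.2 reads. Values came in steps of bases and not of whole reads, so whole reads were not recovered for nearly all genes and tests on counts were not run. Expected sampling error is thus small for genes of several FPKM and large for those near the filter.

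Values were analysed as log2(FPKM + 1). A fold change on this scale understates the change of genes with low values, and ratios of mean FPKM are named as such. Genes with a mean of at least 1 FPKM over the 6 libraries were tested (12350 genes). TNF was compared with Ctrl by limma (version 3.58.1 in R 4.3.3) with a moderated test, a mean-dependent prior variance and the group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design was fixed as a choice between this test and a count model depending on the unit, before the data were examined.

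The 28 gene lists (582 genes, 568 of them in the table) were also fixed before the data were examined. A list was tested if at least 3 members passed the filter, which left 27. The test was limma's camera with a preset correlation between genes of 0.01, adjusted over the 27 lists; camera with a correlation estimated from the data was an alternative. The fry test was also run; it asks whether the genes of a list move on balance one way and, unlike camera, does not compare them with other genes. Counts of members use the adjustment over all tested genes, and counts adjusted over the list alone are given beside them. Shares of fragments were compared by exact permutation tests. The genes named were the 15 largest rises and 15 largest falls among called genes with a symbol, no overlap between groups and a mean of at least 5 FPKM in the higher group, without predicted gene models; the up to 4 members of each list with the smallest p, or the 2 with the highest level where none passed; and Tnf, Tnfrsf1a, Tnfrsf1b, Nfkbia, Tnfaip3, Lgr5, Mki67, Muc2 and Krt20 whatever their result. Other genes are named where a count was small or a member went against its list, and these were chosen after their values were seen.

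The procedure was tested on simulated data for the same comparison with 12350 genes, of which 50 each were changed by 1.25, 1.5, 2 and 4 times. It recovered 26%, 74%, 86% and 96% of these, and made 8 false calls (5.37% of all calls). Of 100 lists without changed genes, it called 1 at an unadjusted p under 0.05. The simulated genes varied independently of each other, so this does not test the list test where members are correlated. In the real lists the estimated correlation reached 0.824, for glycolysis and hypoxia genes. It was -0.025 for NF-κB, -0.020 for cytokine and -0.017 for M cell genes, under the preset 0.01. The larger p-values of these lists with an estimated correlation thus do not come from correlated members. In the real libraries 2969 genes were called, far more than were changed in the simulation, so the recovered shares may differ there. The median standard error of a log2 change in the real libraries was 0.07.

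The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, a prior without mean trend, sample weights, the replicate number as a block, each library left out in turn, and a minimum absolute log2 change of 1. Chosen after seeing the data were a test of protein-coding genes only and a fit without Ctrl 1 and TNF 3. All 6 libraries and their value columns were used. Results of some genes that the naming rule took are not reported here. Scripts ran in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.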

Results

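Messenger RNA was measured by RNA sequencing in organoids grown from crypts of the large intestine of C57BL/6J mice, an inbred laboratory strain. Colon organoids are small hollow bodies of epithelium that grow in a gel of basement membrane proteins and hold dividing crypt cells and differentiated cells. After 2 days in culture they were kept for 24 hours either without an addition (Ctrl, 3 samples) or with tumour necrosis factor alpha (TNF, 3 samples), a cytokine released during inflammation. The dose of TNF was not given in the sources used here. The comparison asks which genes differ in level between TNF-treated and untreated organoids. The libraries held 4.18 to 4.80 gigabases of sequence assigned to genes, about 28100000 to 32200000 reads, as recovered from the deposited values. Between 12254 and 12458 genes reached 1 FPKM (fragments per kilobase of transcript, scaled to the fragments of the library) in a library. Nothing in the labels says that the samples of a group came from separate cultures or animals, so the p-values below measure only the spread between these samples, which may be technical.

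With TNF, the organoids held more RNA of most tested NF-κB pathway, cytokine, epithelial defence and MHC class I genes, and less RNA of most tested fatty acid oxidation genes, of most small intestine enterocyte markers and of the gasdermin C genes Gsdmc2, Gsdmc3 and Gsdmc4. By log2(FPKM + 1), complement component C3 had the largest rise among the called genes with at least 5 FPKM in the higher group, from 3.73 ± 0.270 FPKM in Ctrl to 76.3 ± 5.74 FPKM in TNF (mean ± SD, n = 3 in each group, as for all values below). On the same scale the gasdermin gene Gsdmc4 had the largest fall, from 26.8 ± 4.25 to 1.69 ± 0.185 FPKM. As ratios of mean FPKM, Slc2a6 rose more than C3 (22.8-fold against 20.5-fold) and Gsdmc2 fell more than Gsdmc4 (18.4-fold against 15.9-fold). Of 12350 genes with a mean of at least 1 FPKM, 2969 differed at an adjusted p below 0.05 by limma, 1595 higher and 1374 lower in TNF. Most of these differences were small, with median log2 changes of 0.36 among the higher and -0.32 among the lower genes. On log2(FPKM + 1), 169 genes were higher and 60 lower with an absolute log2 change of at least 1. Genes with a larger ratio of mean FPKM can fall short of this limit, as with Lif (2.37-fold, log2 change 0.98). In 2962 of the 2969 genes the 3 TNF values lay on one side of the 3 Ctrl values, and 41.4% of all tested genes separated in this way, where chance gives 10%. Leaving out Ctrl 1 brought the count of lower genes to 913, and leaving out both Ctrl 1 and TNF 3, which had the lowest values of the macrophage gene Lyz2, left 821 higher and 596 lower genes with 2 samples in each group.

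Of the 15 largest rises, 4 were in genes of the epithelial defence list (C3, Nos2, Duoxa2 and Duox2). C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136 in GRCm38) had a log2 change of 4.03 (SE 0.07, limma adjusted p = 2.2e-07). Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), rose from 3.49 ± 0.549 to 56.4 ± 5.20 FPKM (log2 change 3.68, SE 0.10, adjusted p = 8.64e-07). The hydrogen peroxide-forming oxidase Duox2 rose from 10.96 ± 0.996 to 65.05 ± 1.91 FPKM, and its maturation factor Duoxa2 from 5.59 ± 1.51 to 45.6 ± 5.34 FPKM. Ang4, a ribonuclease with antimicrobial activity, rose from 28.3 ± 2.64 to 202.5 ± 10.6 FPKM. Guca2b, which encodes uroguanylin, an intestinal peptide ligand of guanylate cyclase C (ENSMUSG00000032978, chromosome 4, 119656607 to 119658954), rose from 6.28 ± 0.945 to 63.3 ± 5.99 FPKM (log2 change 3.15, SE 0.10, adjusted p = 2.35e-06). The other rises were in Icam1 (16.7-fold), the sugar transporter gene Slc2a6 (22.8-fold), AW112010 (7.73-fold), the cytokine gene Flt3l (16.4-fold), Ecscr (9.04-fold), the metalloreductase gene Steap4 (8.02-fold), Nfkbia, Tnfaip3 and Tnf, as ratios of mean FPKM. Exons of Icam1, Duoxa2, Flt3l and Ecscr, and among the largest falls those of Slc37a2, overlap exons of other genes, so part of their values can come from the neighbour. In all, exons of 30 of the 119 genes that the naming rule took overlap another gene.

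The 15 largest falls were led by 2 gasdermin C genes. Gsdmc4 (ENSMUSG00000055748, chromosome 15, 63891264 to 63912297) had a log2 change of -3.36 (SE 0.11, adjusted p = 2.23e-06), and its neighbour Gsdmc2 (chromosome 15, 63824346 to 63845177) fell from 13.8 ± 3.22 to 0.751 ± 0.203 FPKM (log2 change -3.06, SE 0.16, adjusted p = 1.7e-05). Cyp2w1, a cytochrome P450 gene, fell from 6.44 ± 1.15 to 0.417 ± 0.0377 FPKM, and Slc37a2, a sugar phosphate transporter gene, from 7.82 ± 2.68 to 0.819 ± 0.247 FPKM. Hsd11b2, whose enzyme inactivates glucocorticoids, fell from 45.2 ± 5.49 to 12.3 ± 0.423 FPKM, and Hpgd, whose enzyme degrades prostaglandins, from 73.4 ± 3.44 to 28.4 ± 0.509 FPKM. The urea cycle gene Otc, the carboxylesterase gene Ces2a, intestinal alkaline phosphatase (Alpi), the glutathione transferase gene Gstm3, the aldehyde dehydrogenase genes Aldh1a1 and Aldh1a7, the growth factor gene Bmp3 and the peptidase gene Enpep were also among them, with log2 changes from -1.74 for Otc to -1.33 for Enpep. The gasdermin C, carboxylesterase, Aldh1a, Gstm and cytochrome P450 genes have close paralogs, and the counting of reads shared between them was not given in the sources used here, so the split among members is uncertain.

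**Figure D1:**
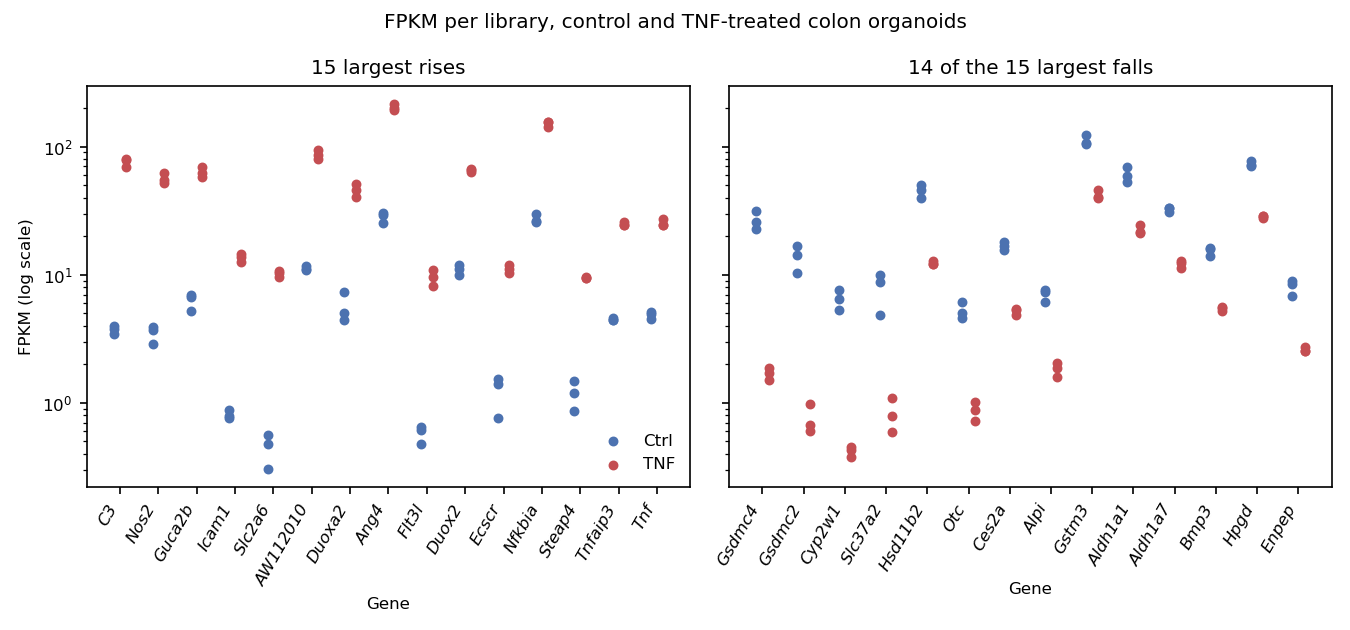
FPKM of each library (log axis) for the 15 genes with the largest rise and 14 of the 15 with the largest fall by log2 change among called genes with a mean of at least 5 FPKM in the higher group; blue points are the 3 Ctrl and red points the 3 TNF libraries. The 3 TNF points of each gene lie on one side of the 3 Ctrl points, from C3 (3.73 to 76.3 FPKM on average) to Gsdmc4 (26.8 to 1.69 FPKM).

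Genes of the NF-κB pathway rose almost throughout. Of 22 tested members, 20 rose, none fell and 2 (Birc2 and Sdc4) did not pass, and 21 passed when adjusted over the list alone. Nfkbia, the inhibitor that NF-κB itself induces, rose from 27.1 ± 2.10 to 151.0 ± 7.12 FPKM. The deubiquitinase gene Tnfaip3 rose from 4.51 ± 0.0921 to 24.99 ± 0.639 FPKM, the adhesion molecule Icam1 from 0.815 ± 0.0602 to 13.6 ± 0.964 FPKM and the apoptosis inhibitor Birc3 from 7.36 ± 0.696 to 31.0 ± 0.815 FPKM. The list stood above the other genes by camera (adjusted p = 1.43e-19 over 27 lists), and it was the 1 list of the 27 that also passed with an estimated correlation (adjusted p = 0.0132). Tnf itself rose from 4.86 ± 0.348 to 25.5 ± 1.68 FPKM (log2 change 2.18, adjusted p = 1.32e-06). Of the receptors, Tnfrsf1b rose from 8.24 ± 0.155 to 16.4 ± 0.33 FPKM, and Tnfrsf1a was at 27.3 ± 0.356 and 26.6 ± 1.85 FPKM (log2 change -0.04, adjusted p = 0.647).

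Cytokine and chemokine genes moved mostly upwards. Of 15 tested members, 10 rose, 2 fell and 3 did not pass (13 adjusted over the list alone). Of the leukocyte attractants, Cxcl16 rose from 11.2 ± 0.316 to 34.2 ± 1.247 FPKM and Ccl20 from 1.91 ± 0.375 to 9.88 ± 0.483 FPKM, while Lif, an interleukin-6 family cytokine, rose from 2.46 ± 0.183 to 5.84 ± 0.365 FPKM. The members that fell were Il18 and Ccl28, with log2 changes of -0.76 and -0.20. By camera the list passed (adjusted p = 6.7e-05) and did not pass with an estimated correlation (adjusted p = 0.0583). Another 15 members, among them Cxcl2, Cxcl5, Il1b and Il6, had a mean under 1 FPKM and were not tested.

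Defence genes of the epithelium were among the most strongly raised. Of 13 tested, 9 rose, 2 fell and 2 did not pass (12 adjusted over the list alone). Besides C3, Nos2 and Duox2, the superoxide-forming oxidase Nox1 rose from 66.3 ± 0.996 to 217.3 ± 2.91 FPKM, with exons that overlap Cstf2. Dmbt1, a mucosal scavenger receptor gene, and complement factor B (Cfb) fell, with log2 changes of -1.02 and -0.47. The list passed camera (adjusted p = 1.11e-06), and its adjusted p with an estimated correlation was 0.116.

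MHC class I genes rose in 13 of 14 tested members, and the remaining one, H2-T23, did not pass; all 14 passed when adjusted over the list alone. B2m, the light chain of MHC class I, rose from 165.7 ± 8.65 to 357.8 ± 8.36 FPKM, the peptide-loading factor Tapbp from 21.8 ± 2.10 to 59.3 ± 3.17 FPKM, the immunoproteasome subunit Psmb10 from 12.8 ± 1.07 to 24.0 ± 0.410 FPKM and the paralog-rich H2-Q4 from 7.36 ± 0.628 to 16.0 ± 1.9 FPKM. As a list they passed camera (adjusted p = 2.03e-10), with an adjusted p of 0.0583 with an estimated correlation. Among interferon-stimulated genes, 9 of 20 rose, none fell and 11 did not pass (11 passed adjusted over the list alone). The transcription factor Irf1 rose 2.95-fold, the RNA sensor Ddx58 1.93-fold, Parp14 2.12-fold and Cmpk2 1.9-fold, while Isg15 had a log2 change of 0.52 that did not pass. That list passed camera (adjusted p = 3.37e-05) and did not with an estimated correlation (adjusted p = 0.0809). Of 5 MHC class II genes tested, Cd74 rose from 3.65 ± 1.14 to 13.0 ± 0.544 FPKM, Ifi30 fell from 140.2 ± 8.82 to 117.0 ± 6.16 FPKM and 3 did not pass (camera adjusted p = 0.306; 2 passed adjusted over the list alone). The call for Ifi30 was lost without TNF 1 (adjusted p = 0.0534) and without TNF 2 (adjusted p = 0.0648). The pan-leukocyte gene Ptprc, below the 1 FPKM filter, was at 0.179 ± 0.0287 FPKM in Ctrl and 0.378 ± 0.00453 FPKM in TNF.

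M cell markers, genes of the epithelial cells that pass antigens to lymphoid tissue, rose in 7 of 9 tested members and 2 did not pass (7 adjusted over the list alone). Pglyrp1, a peptidoglycan-binding protein gene also on the defence list, rose from 56.8 ± 4.89 to 191.4 ± 9.15 FPKM. Tnfrsf11a, the receptor for RANKL, rose from 11.5 ± 0.279 to 20.2 ± 0.907 FPKM and Marcksl1 from 26.0 ± 0.714 to 38.0 ± 1.10 FPKM, and Ccl20 is shared with the cytokine list. Camera gave the M cell list an adjusted p of 7.43e-08, with an adjusted p of 0.0543 with an estimated correlation. Fetal-like and regenerative epithelium genes rose in 9 of 16 tested members, none fell and 7 did not pass (10 adjusted over the list alone). Ly6a, which encodes the surface protein Sca-1, rose from 111.2 ± 12.2 to 194.7 ± 17.3 FPKM, Sprr1a from 89.5 ± 18.3 to 209.1 ± 28.3 FPKM, Krt7 from 27.3 ± 1.67 to 36.9 ± 1.27 FPKM and the growth factor gene Areg from 37.6 ± 4.48 to 57.8 ± 3.99 FPKM. This list passed camera (adjusted p = 0.000488) and did not with an estimated correlation (adjusted p = 0.421).

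**Figure D2:**
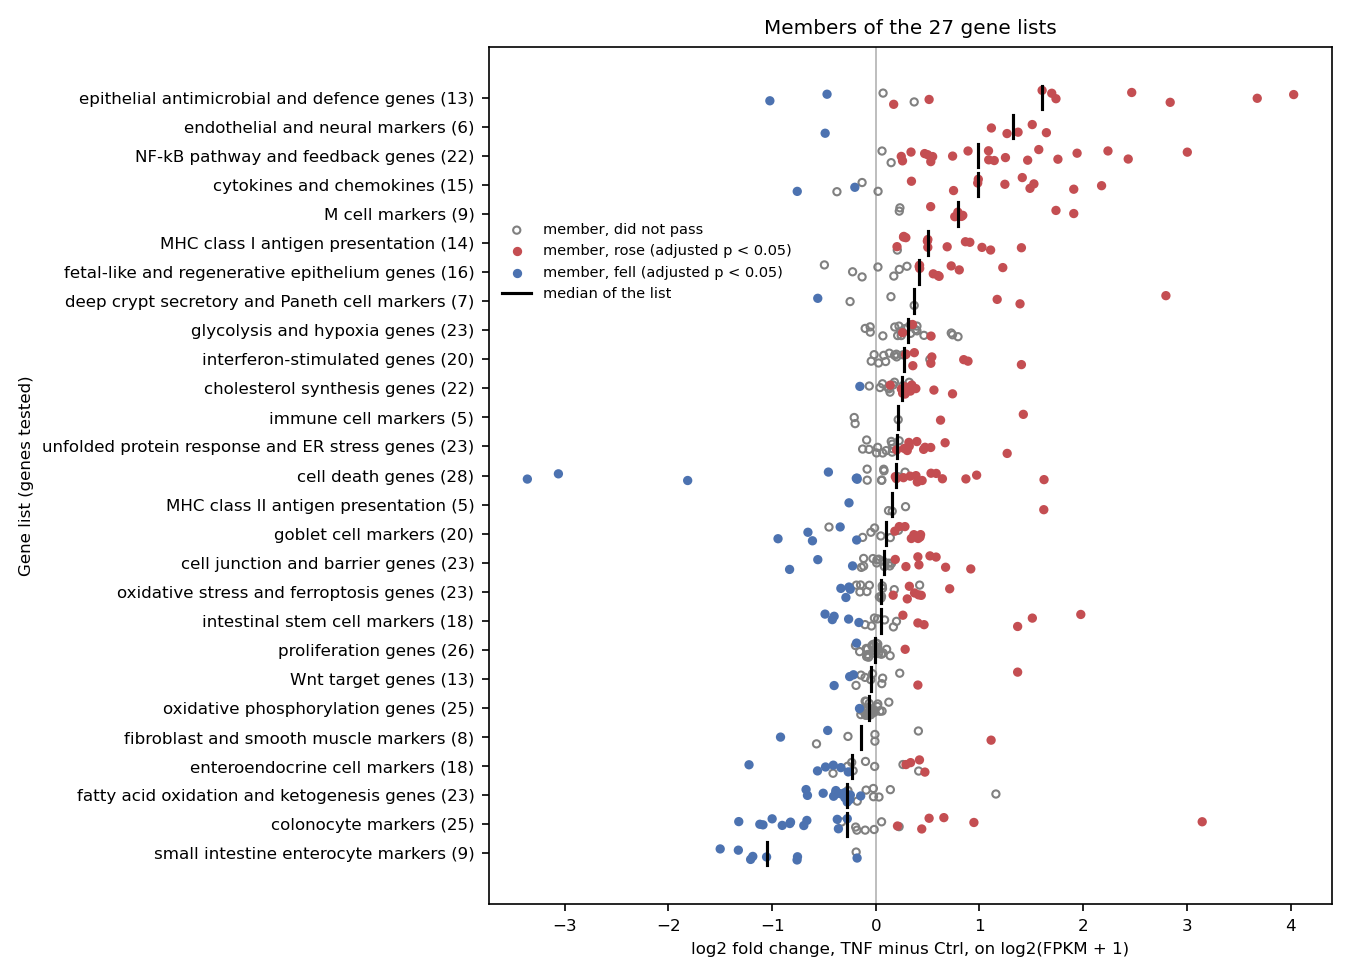
Log2 fold change (TNF minus Ctrl, on log2(FPKM + 1)) of each tested member of 27 gene lists, with the number of genes tested in parentheses; filled red points rose, filled blue points fell, open points did not pass, and black bars are medians. The medians run from 1.60 for epithelial defence genes to -1.05 for small intestine enterocyte markers, and the list medians of proliferation, Wnt target and oxidative phosphorylation genes lie within 0.10 of 0.

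Stem cell markers moved in both directions. Of 18 tested, 6 rose, 5 fell and 7 did not pass (12 adjusted over the list alone). Lgr5, the Wnt-dependent marker of crypt base stem cells, fell from 46.3 ± 2.28 to 34.8 ± 0.218 FPKM (log2 change -0.40, SE 0.05, adjusted p = 0.000638), as did Smoc2, Rgmb, Cdca7 and Bmi1. The stem cell transcription factor Ascl2 rose from 3.80 ± 0.278 to 11.4 ± 0.861 FPKM, Tnfrsf19 from 1.21 ± 0.255 to 5.28 ± 0.422 FPKM and Olfm4 from 0.215 ± 0.0440 to 3.82 ± 0.758 FPKM. The list did not pass camera (adjusted p = 0.319), which compares it with the other genes. It passed only by fry (adjusted p = 0.00968), which asks whether members move on balance one way and makes no comparison with other genes. Wnt target genes gave 2 rises (Ascl2 and Cd44), 3 falls (Lgr5, Ccnd1 and Znrf3) and 8 members that did not pass out of 13 (5 adjusted over the list alone; camera adjusted p = 0.687). Their median log2 change was -0.05, their mean 0.06 and the camera direction downward. Cd44 rose from 31.3 ± 1.86 to 41.7 ± 2.59 FPKM, and Ccnd1 fell from 26.9 ± 0.0560 to 23.1 ± 0.954 FPKM. The call for Ccnd1 was lost without both Ctrl 1 and TNF 3 (adjusted p = 0.0597). Most proliferation genes did not pass: of 26 tested, Bub1 rose (11.6 ± 0.153 to 14.4 ± 0.366 FPKM), Plk1 fell (53.5 ± 2.94 to 46.9 ± 0.811 FPKM) and 24 did not pass (1 adjusted over the list alone; camera adjusted p = 0.641). Mki67 was at 94.3 ± 2.13 and 96.2 ± 5.92 FPKM (log2 change 0.03, adjusted p = 0.753). The call for Plk1 was lost when any sample other than Ctrl 2 was left out (adjusted p 0.0592 to 0.0914).

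Colonocyte markers fell more often than they rose. Of 25 tested, 12 fell, 6 rose and 7 did not pass (21 adjusted over the list alone). The cytochrome P450 gene Cyp2c55 fell from 890.0 ± 44.2 to 409.6 ± 24.8 FPKM, the fatty acid-binding protein gene Fabp2 from 71.4 ± 8.71 to 27.9 ± 2.17 FPKM and Tmigd1 from 27.6 ± 1.93 to 12.4 ± 0.617 FPKM. The members that rose were Guca2b, its relative Guca2a (guanylin), the water channel gene Aqp4, Lypd8, which restrains flagellated bacteria, and the adhesion genes Ceacam1 and Ceacam20, with log2 changes from 0.21 to 3.15. Krt20 was at 83.1 ± 16.8 and 65.2 ± 4.68 FPKM and did not pass (adjusted p = 0.11), and it passed without Ctrl 1 (log2 change -0.46, adjusted p = 0.0314). The list passed camera in the downward direction (adjusted p = 0.0135) and did not with an estimated correlation (adjusted p = 0.509). Markers of small intestine enterocytes, measured here in colon cultures, fell in 8 of 9 tested members and the other did not pass (8 adjusted over the list alone). Apob fell from 55.6 ± 3.16 to 26.3 ± 1.41 FPKM, the brush border peptidase gene Anpep from 9.28 ± 1.28 to 3.08 ± 0.223 FPKM, Alpi from 7.02 ± 0.739 to 1.83 ± 0.219 FPKM and the bile acid transporter gene Slc10a2 from 20.9 ± 1.61 to 11.9 ± 0.731 FPKM. This list passed camera (adjusted p = 6.04e-08), with an adjusted p of 0.0583 with an estimated correlation.

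Goblet cell markers split. Of 20 tested, 8 rose, 5 fell and 7 did not pass (15 adjusted over the list alone; camera adjusted p = 0.641). The main mucin gene Muc2 was at 349.5 ± 28.2 and 360.7 ± 6.23 FPKM (log2 change 0.05, adjusted p = 0.625). Retnlb fell from 93.5 ± 8.63 to 48.0 ± 1.35 FPKM, Fcgbp from 408.4 ± 21.6 to 267.2 ± 18.1 FPKM and Klk1 from 137.8 ± 4.28 to 108.4 ± 2.27 FPKM, whereas the mucin-folding gene Agr2 rose from 263.2 ± 12 to 354.0 ± 13.7 FPKM. The list's median log2 change was 0.09 and its mean -0.01. Among 7 deep crypt secretory and Paneth cell markers, Ang4, Mmp7 (2.00 ± 0.560 to 6.80 ± 0.784 FPKM) and Pla2g2a (0.937 ± 0.774 to 3.19 ± 0.680 FPKM) rose, Reg4 fell from 1101 ± 38.3 to 747.9 ± 59.9 FPKM, and 3 did not pass (5 adjusted over the list alone). That list did not pass camera (adjusted p = 0.0546), and it passed without Ctrl 1, Ctrl 3 or TNF 2 (adjusted p 0.0290 to 0.0413) and with a pseudocount of 5 (0.0499), quantile normalization (0.0399), the replicate number as a block (0.0248) or without both Ctrl 1 and TNF 3 (0.0319); fry, without the comparison with other genes, gave 0.000588. Pla2g2a is annotated as a polymorphic pseudogene, and its call was lost without TNF 1 (adjusted p = 0.0529). Enteroendocrine markers gave 4 rises, 6 falls and 8 members that did not pass out of 18 (12 adjusted over the list alone). The list did not pass camera (adjusted p = 0.181), and it passed with a filter at 5 FPKM (0.00726); fry, without the comparison with other genes, gave 0.0157. The proglucagon gene Gcg fell from 36.6 ± 2.99 to 15.2 ± 2.00 FPKM, the granin gene Chgb from 81.2 ± 3.50 to 64.1 ± 1.34 FPKM and the neurotensin gene Nts from 9.58 ± 0.158 to 6.58 ± 0.661 FPKM, while Scg2 rose from 1.87 ± 0.146 to 2.84 ± 0.174 FPKM. Of 20 tuft cell markers only Ptpn18 reached the filter, at 7.002 ± 0.530 and 6.73 ± 0.426 FPKM (adjusted p = 0.645), so the list was not tested; Rgs13 was at 0.682 ± 0.148 and 0.762 ± 0.193 FPKM.

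**Figure D3:**
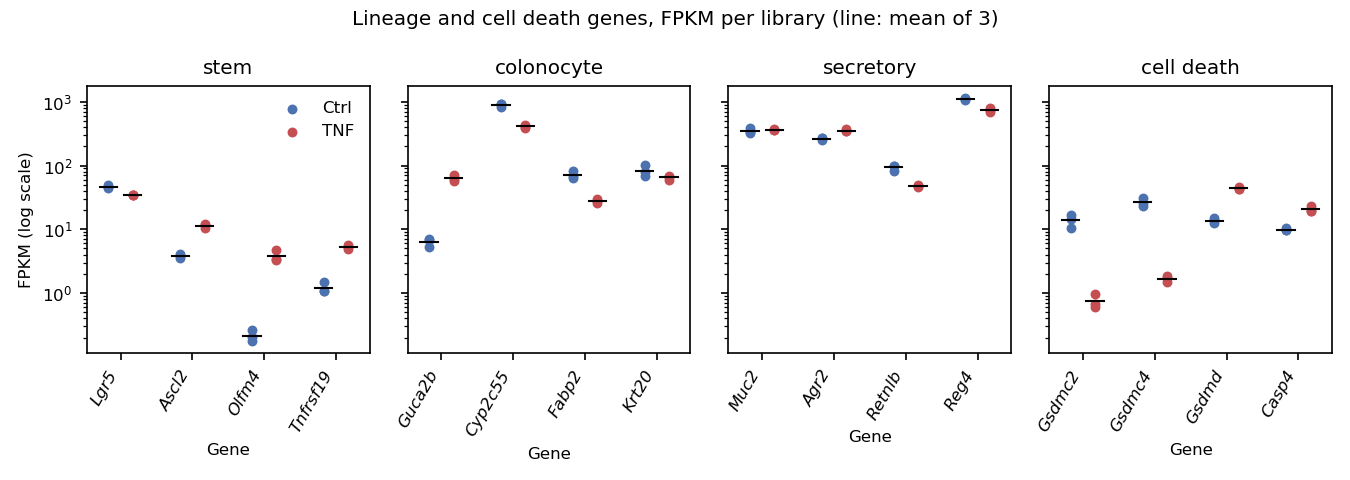
FPKM of each library (log axis) for 4 stem cell, 4 colonocyte, 4 secretory and 4 cell death genes; blue points are the 3 Ctrl and red points the 3 TNF libraries, and black lines are group means. Within each panel genes go both ways, as with Lgr5 (46.3 to 34.8 FPKM) and Ascl2 (3.80 to 11.4 FPKM), or Gsdmc4 (26.8 to 1.69 FPKM) and Gsdmd (13.7 to 44.2 FPKM).

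Of 28 cell death genes tested, 13 rose, 7 fell and 8 did not pass (21 adjusted over the list alone). Gsdmd, whose product forms pores in pyroptosis, rose from 13.7 ± 1.24 to 44.2 ± 1.53 FPKM (log2 change 1.62, SE 0.07, adjusted p = 5.04e-06), and Casp4, the caspase that cleaves it in response to lipopolysaccharide, from 9.90 ± 0.327 to 20.4 ± 2.09 FPKM. Gsdmc2, Gsdmc3 and Gsdmc4, of the same pore-forming family, fell. Casp8, Ripk3 and Mlkl, of the extrinsic apoptosis and necroptosis pathways, rose with log2 changes of 0.53, 0.27 and 0.58. The list's median log2 change was 0.19 and its mean -0.04; it did not pass camera (adjusted p = 0.0546). It passed without TNF 1 (adjusted p = 0.0437) and with no filter (0.0165), a filter at 5 FPKM (0.0493), a pseudocount of 5 (0.0495), quantile normalization (0.0419) or sample weights (0.0462), and fry, without the comparison with other genes, gave 0.0058. Of 23 junction and barrier genes, 8 rose, 3 fell and 12 did not pass (16 adjusted over the list alone). Claudin 4 (Cldn4) rose from 106.9 ± 7.51 to 202.5 ± 11.3 FPKM, F11r from 57.2 ± 2.90 to 86.0 ± 1.43 FPKM, β-catenin (Ctnnb1) from 175.9 ± 4.96 to 253.1 ± 5.98 FPKM and the myosin light chain kinase gene Mylk from 1.46 ± 0.0392 to 2.93 ± 0.156 FPKM, while Cldn8, Cldn2 and Cldn15 fell. The junction list passed camera (adjusted p = 0.0394) and did not with an estimated correlation (adjusted p = 0.369), nor without Ctrl 1 (adjusted p = 0.0786), Ctrl 2 (0.0537) or TNF 3 (0.0597).

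Fatty acid oxidation and ketogenesis genes fell in 15 of 23 tested members, none rose and 8 did not pass. Adjusted over the list alone 18 passed, of which 16 fell and 2 rose. Hadh fell from 45.9 ± 2.48 to 28.7 ± 1.28 FPKM, Acot1 from 8.54 ± 0.565 to 4.99 ± 0.359 FPKM, Acadm from 24.6 ± 0.513 to 18.3 ± 0.734 FPKM and Hadha from 33.4 ± 0.505 to 26.99 ± 0.327 FPKM. As a list they passed camera (adjusted p = 2.56e-06) and did not with an estimated correlation (adjusted p = 0.117). Cholesterol synthesis genes rose in 11 of 22 tested members, 1 fell (Stard4) and 10 did not pass (15 adjusted over the list alone). Mvd rose from 25.9 ± 2.49 to 43.8 ± 3.29 FPKM, Fdps from 33.0 ± 4.22 to 49.0 ± 2.94 FPKM and Sc5d from 20.2 ± 1.18 to 25.8 ± 1.59 FPKM. This list passed camera (adjusted p = 6.59e-05), with an adjusted p of 0.420 with an estimated correlation. Unfolded protein response genes rose in 11 of 23 tested members, none fell and 12 did not pass (13 adjusted over the list alone). The sensor kinase gene Ern1 rose from 7.31 ± 0.857 to 19.0 ± 1.19 FPKM, and Herpud1, Dnajb9 and Pdia6 rose by log2 changes of 0.32, 0.40 and 0.32. This list had a camera adjusted p of 3.28e-05, and of 0.224 with an estimated correlation.

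In glycolysis and hypoxia genes, 3 of 23 rose, none fell and 20 did not pass (2 adjusted over the list alone). Hexokinase 2 (Hk2) rose from 22.8 ± 0.983 to 33.5 ± 2.37 FPKM, Hk1 1.21-fold and the glucose transporter gene Slc2a1 1.28-fold. This list passed by camera (adjusted p = 0.00126) and did not pass with an estimated correlation (adjusted p = 0.618), and fry, without the comparison with other genes, gave an adjusted p of 0.199. The call for Hk1 was lost without both Ctrl 1 and TNF 3 (adjusted p = 0.0886), and that for Slc2a1 without Ctrl 1, Ctrl 3, TNF 1 or TNF 3 (adjusted p 0.103 to 0.116). Of 25 oxidative phosphorylation genes, Uqcrc1 fell from 58.5 ± 0.972 to 52.3 ± 2.38 FPKM and 24 did not pass (0 adjusted over the list alone). That call was lost when any sample other than TNF 3 was left out (adjusted p 0.0501 to 0.118). The list did not pass camera (adjusted p = 0.0546), and it passed without Ctrl 3 (adjusted p = 0.00264) or TNF 3 (adjusted p = 0.0123), without both Ctrl 1 and TNF 3 (0.0165) and with no filter (0.00748). Genes of the mitochondrial chromosome took 8.63% ± 0.172 of the fragments in Ctrl and 8.12% ± 0.181 in TNF, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. Cytosolic ribosomal protein genes took 3.11% ± 0.218 and 2.94% ± 0.0681 (exact permutation p = 0.3), and the 10 genes with the most fragments 9.61% ± 0.131 and 9.01% ± 0.160 (exact permutation p = 0.1). Most of these 10 are genes of the mitochondrial chromosome, led by mt-Co1 at 3.61% on average, so this share largely repeats the mitochondrial one. Oxidative stress and ferroptosis genes gave 7 rises, 4 falls and 12 members that did not pass out of 23 (12 adjusted over the list alone; camera adjusted p = 0.444). Gpx2 rose from 259.2 ± 12.1 to 345.0 ± 3.13 FPKM, Hmox1 from 7.78 ± 1.10 to 13.3 ± 1.12 FPKM, and Srxn1 and Slc7a11 rose 1.36-fold and 1.32-fold.

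Markers of cells outside the epithelium were low, and some of them differed. Of 6 endothelial and neural markers tested, 5 rose and 1 fell (6 adjusted over the list alone). The members that rose are known from glia and neurons. Among them, Gfap went from 1.76 ± 0.368 to 7.60 ± 0.884 FPKM, S100b from 1.10 ± 0.336 to 4.02 ± 0.351 FPKM, Tubb3 from 1.29 ± 0.237 to 3.96 ± 0.457 FPKM and Uchl1 from 1.14 ± 0.372 to 4.51 ± 0.534 FPKM. The member that fell, Lyve1, is known from lymphatic endothelium. The list passed camera (adjusted p = 0.000328) and did not with an estimated correlation (adjusted p = 0.203). Of 5 immune cell markers tested, Trbc2, a T cell receptor constant gene (0.234 ± 0.203 to 2.29 ± 0.406 FPKM), and Laptm5 (0.817 ± 0.319 to 1.78 ± 0.190 FPKM) rose and 3 did not pass (2 adjusted over the list alone; camera adjusted p = 0.181, and 0.00449 with no filter). The call for Laptm5 was lost without TNF 1 (adjusted p = 0.0597) or TNF 2 (adjusted p = 0.0536). Within groups, the macrophage gene Lyz2 was low in Ctrl 1 (4.65 FPKM) and TNF 3 (2.72 FPKM) and between 15.6 and 16.0 FPKM in the other 4 libraries. Of 8 fibroblast and smooth muscle markers, Thy1, which T cells and neurons also carry, rose from 0.682 ± 0.310 to 2.60 ± 0.246 FPKM, the collagen genes Col1a1 (3.03 ± 1.59 to 1.03 ± 0.146 FPKM) and Col3a1 (1.92 ± 0.288 to 1.11 ± 0.0736 FPKM) fell, and 5 did not pass (3 adjusted over the list alone; camera adjusted p = 0.588). Without both Ctrl 1 and TNF 3 the call for Col3a1 was lost (adjusted p = 0.0862), and the call for Col1a1 was lost without Ctrl 2, TNF 1, TNF 2 or TNF 3 (adjusted p 0.0537 to 0.0905).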

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

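The protein-coding restriction and the joint omission of Ctrl 1 and TNF 3 were chosen after the data were seen. Across pseudocounts, filters, scalings, prior, sample weights and protein-coding genes only, the count of 2969 genes ranged from 2197 to 3416. Similar counts did not always mean the same genes. With no filter 2758 genes passed, of which 2003 were among the 2969. The median log2 change of all tested genes was -0.00183 after median-of-ratios scaling and -0.0138 after quantile normalization. Higher genes made up 53.7% of the calls, 53.2% after median-of-ratios scaling (1583 higher, 1390 lower), 49.0% after quantile normalization (1480 higher, 1543 lower), 52.3% with a filter at 5 FPKM (1148 higher, 1049 lower) and 62.9% with no filter (1734 higher, 1024 lower). Leaving out each library in turn gave 2072 to 2607 genes, 1149 to 1430 of them higher and 913 to 1177 lower; the 913 came without Ctrl 1. With Ctrl 1 and TNF 3 both left out, 1417 genes passed (821 higher, 596 lower), of which 1360 were among the 2969; fewer samples were fitted. A minimum log2 change of 1 kept 229 genes (169 higher, 60 lower), by construction. The number of lists by camera ranged from 14 to 18 against 15, except that 1 list (NF-κB) passed with an estimated correlation. With a filter at 5 FPKM only 24 lists could be tested, and of the 15 that passed there 13 were among those of the main test. The endothelial and neural list then had too few members to be tested. The lists that did not pass in the main test and passed by camera under 1 or more alternatives were cell death, deep crypt and Paneth, enteroendocrine, oxidative phosphorylation and immune genes; the junction list was lost with a filter at 5 FPKM (adjusted p = 0.0968), with protein-coding genes only (0.0527) and without Ctrl 1 and TNF 3 (0.129). The fry test makes no comparison with other genes and so answers another question; the stem cell list passed by it alone. Of the 113 named genes that passed, 106 to 111 kept their call when 1 library was left out, 106 with no filter, 105 without both Ctrl 1 and TNF 3, 109 with the replicate number as a block, 110 without the mean trend, and 113 under either pseudocount or scaling; none changed direction.

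Directions turned in results that did not pass. The stem cell list pointed down with a filter at 5 FPKM (adjusted p = 0.858), the Wnt target list up by fry (adjusted p = 0.267), the fibroblast list up without Ctrl 1 and TNF 3 (adjusted p = 0.950), the proliferation list up without TNF 2 (adjusted p = 0.930; 0.321 to 0.969 over the libraries left out), and Mki67 had a log2 change of -0.0217 without TNF 1 (-0.0217 to 0.0621 over the libraries left out). The cause was not tested.

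The replicate numbers were checked as a pairing. Deviations of same-numbered samples correlated at -0.004, -0.101 and 0.005, and not every sample correlated best with its own number, so the numbers were not taken as pairs. With the replicate number as a block, 2260 genes (1256 higher, 1004 lower) and 16 lists passed. The named genes that lost their call by limma with this block were Ifi30 (adjusted p = 0.0596), Plk1 (0.0703), Uqcrc1 (0.0757) and Slc2a1 (0.0831).

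The edgeR test, planned for a table of raw counts, was not run, because the table holds FPKM and whole reads could not be recovered. Depth limits calls near the filter: at 1 FPKM a transcript of 1 kilobase had 28.1 to 32.2 reads.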

Other observations

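The gene families, the splits of the samples, and the tests of depth, fibroblast markers and colonocyte shares were chosen after the results were seen, while the second macrophage list and the second glia list were written before their values were seen. Genes that share a symbol stem were tested as families by camera (328 families of tested genes, of which 9 passed upwards and 4 downwards; none passed with an estimated correlation, adjusted p = 0.967). Of 24 cytochrome P450 genes, 18 fell and 2 rose (adjusted p = 1.83e-08), among them Cyp2c65 (134.9 ± 9.52 to 71.2 ± 0.817 FPKM), Cyp3a13 (39.3 ± 4.55 to 16.7 ± 0.691 FPKM) and Cyp2b10 (23.7 ± 1.85 to 9.34 ± 1.16 FPKM); the 2 that rose were Cyp51, of cholesterol synthesis, and Cyp4v3. All 8 carboxylesterase genes fell (adjusted p = 1.7e-06), as with Ces2e (60.04 ± 4.55 to 29.6 ± 3.92 FPKM), and 5 of 7 Gstm glutathione transferase genes fell (adjusted p = 0.00219), as with Gstm1 (272.7 ± 33.5 to 137.1 ± 13.7 FPKM). Of 17 aldehyde dehydrogenase genes, 8 fell and Aldh1a3 rose, from 11.98 ± 1.39 to 24.6 ± 4.13 FPKM (family adjusted p = 0.00734). The Ugt glucuronosyltransferase genes (4 fell and 1 rose of 10, adjusted p = 0.0856) and the Sult sulfotransferase genes (3 fell and 1 rose of 6, adjusted p = 0.532) did not pass. These families hold close paralogs, whose reads can be shared.

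Among the families that rose, 5 of 6 Clca genes did so (adjusted p = 0.000591). Clca3b went from 575.1 ± 40.8 to 1407 ± 37.3 FPKM and Clca4b from 3.08 ± 0.404 to 15.5 ± 0.829 FPKM, while Clca1 was at 6.78 ± 1.38 and 6.67 ± 0.918 FPKM. Of 7 β-tubulin genes 6 rose (adjusted p = 0.00117), with the largest change in Tubb4a (2.61 ± 0.118 to 8.51 ± 0.467 FPKM). Of 12 TNF receptor superfamily genes 8 rose and Tnfrsf21 fell (adjusted p = 0.00734). These 7 families kept their direction and their call under both scalings, with 4 Clca genes called after quantile normalization.

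Macrophage genes differed between libraries of one group, as with Lyz2, which was at 4.65, 16.0 and 15.6 FPKM in Ctrl 1 to 3 and at 15.7, 15.7 and 2.72 FPKM in TNF 1 to 3, and Csf1r and Itgam were also lowest in Ctrl 1 and TNF 3. A candidate explanation is that macrophages were carried over with the crypts in different numbers: in a second list of 24 macrophage genes, none of them on a fixed list, 10 of the 22 with a mean of at least 0.05 FPKM had Ctrl 1 and TNF 3 as their 2 lowest libraries, where chance gives 6.67% (exact binomial p = 5.31e-07, which takes genes as independent). Of these 10, only C1qb, at 2.16 FPKM, had a mean of at least 1 FPKM. Cd52, Pf4 and Aif1, with means under 1 FPKM, were highest in TNF 3 (0.964, 0.562 and 0.320 FPKM). The most abundant members of the list, Apoe, Lcp1 and Lgmn, at 20.8, 17.6 and 16.2 FPKM on average, are known from other cells too and were not among the 10. With these members the list summed to 44.7, 64.7 and 54.7 FPKM in Ctrl 1 to 3. In TNF 1 to 3 it summed to 86.3, 86.7 and 68.3 FPKM, so the sum in TNF 3 was above that of every Ctrl library. Lcp1 was at 22.0 FPKM in TNF 3 and between 12.6 and 14.4 FPKM in Ctrl. Lcp1, Mrc1 and Lgmn passed as higher in TNF (log2 changes 0.65, 0.58 and 0.18). Lower depth is argued against, since TNF 3 was the deepest library (rank 1 of 6).

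Glial and neural genes were higher in the TNF libraries, with Gfap between 7.07 and 8.62 FPKM there and between 1.34 and 2.04 FPKM in Ctrl, and Sox10, a transcription factor of glia, at 0.0693 ± 0.0450 FPKM in Ctrl and 0.295 ± 0.0455 FPKM in TNF. More non-epithelial cells of every kind are argued against by the fibroblast and smooth muscle markers, whose median log2 change was -0.14 (SE 0.242 over 8 genes, taken as independent). This covers fibroblasts and smooth muscle only. Of 5 immune cell markers tested, 2 rose and 3 did not pass. More enteric glia carried over into the TNF libraries may be a source. In a second list of glia genes, 4 rose (Gpm6b, Cryab, Mal and Cnp) and none fell. The other members that reached the 1 FPKM filter, L1cam and Gfra3, did not pass (log2 changes 0.06 and -0.16). Over 12 genes with a mean of at least 0.2 FPKM, tested or not, the median log2 ratio was 0.698 (SE 0.197), between the 0.5 and 1 set as bounds beforehand. The most abundant of these, L1cam and Cnp, at 27.7 and 12.1 FPKM, are known from other cells too. Carry-over cannot be told apart from a response to TNF in glia or in the epithelium, since the list fell between the bounds and no purified cells were measured.

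Colonocyte markers split between 12 that fell and 6 that rose. A lower share of colonocytes in the TNF cultures would lower these markers together, and the 6 that rose, Guca2b by 10.1-fold among them, argue against it as the whole cause. A lower share combined with induction of single genes, and a response to TNF within colonocytes, stay open and were not tested.

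With 6 samples there are 10 splits into groups of 3, so no share under 0.05 is possible. The real split gave 2969 genes and the highest other split 1, so 1 of the 10 splits, the real one itself, gave as many. For the lists, the real split gave 15 and the other splits 5 to 13, so again only the real split itself gave as many. Each other split sets TNF and Ctrl samples on both sides, so part of the TNF difference remains in it. Whether this is why 5 to 13 lists passed there was not tested.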
